A study of Oryctolagus cuniculus with 12 samples.

How the data were processed

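Gene expression was measured by bulk RNA sequencing in 12 libraries from the rabbit (Oryctolagus cuniculus) temporomandibular joint, 3 for each combination of 2 zones (superficial zone and condylar cartilage) and 2 states (control and osteoarthritis, OA). Total RNA was extracted with the RNeasy Micro kit, ribosomal RNA was depleted with QIAseq FastSelect, and directional libraries were made with NEBNext Ultra II, per the labels. The labels do not state whether the control joints were operated on, how long after surgery tissue was collected, or whether both zones came from the same animals. Groups and replicate numbers were taken from the sample titles, which name superficial zone cells and condylar cartilage cells.

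The submitters' processing notes name Trim Galore 0.6.7, STAR 2.7.9a, StringTie 2.1.0, Salmon 1.1.0, DESeq2 1.26.0 and MultiQC 1.13 with the OryCun2.0 genome, without the role or order of each, and per the file headers the feature lengths came from Salmon. The deposited table gives, for each of 14621 genes, an estimated count per library, in whole numbers, with the deposited TPM (transcripts per 1000000) values beside it. The file headers call the counts both normalised and raw. Median-of-ratios factors of 0.556 to 1.57 between the libraries showed counts that were not scaled to 1 depth, and they were used as raw. The TPM columns each sum to 1000000, and the 12 columns of deposited log2 TPM were not used here. The filter that left 14621 genes is not stated, and the highest count of every gene across the libraries was 11 or more. Of these genes, 13317 were annotated as protein-coding and 1125 as long non-coding RNA. Symbols came from the deposited table for 9801 genes and, through the deposited Entrez gene identifier, from a RefSeq naming table (assembly mOryCun1.1) for another 1070. A further 3750 genes had no symbol. Where both sources named a gene, 98.4% of 8472 had the same symbol. The naming table is of another assembly than the counts, so no coordinates are given.

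Estimated counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, TMM normalisation, filterByExpr with a minimum count of 10, 14438 genes tested), in 1 model with the 4 groups as a factor. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. There were 5 comparisons: OA against control in each zone, the difference between those 2 effects (an interaction contrast), and condylar cartilage against superficial zone in control and in OA. Levels are counts per 1000000 of the library total multiplied by its TMM factor (CPM), as mean ± SD over samples, and log2 fold changes are given ± SE. In the edgeR fits this SE is an approximation, the absolute log2 fold change divided by the square root of F. The tests, the gene lists, the named genes and most other settings were chosen before the data were examined, apart from the exceptions stated here. The p-values measure the spread between these samples, since no label ties a replicate to a separate animal.

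The planned model used all 12 libraries as separate samples. Libraries 2 and 3 of the OA superficial zone and libraries 1 and 2 of the OA condylar cartilage proved to be near-duplicates, with a biological coefficient of variation of 0.042 and 0.060 against 0.217 to 0.631 for the other pairs within groups. A chi-square test still found each pair to differ by more than counting noise, and the labels call them biological replicates. Each such pair was nevertheless summed and counted as 1 sample, which left 10 samples, 3 in each control group and 2 in each OA group. This departure was decided after the counts were seen, and the counts from 12 separate libraries stand beside the main ones in the results.

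There were 33 gene lists. The 19 process lists were cartilage matrix, chondrocyte regulators, hypertrophy and mineralisation, superficial zone markers, fibrous matrix, matrix-degrading proteases, protease inhibitors, inflammatory cytokines and NF-kB targets, interferon response, Wnt signalling, TGF-beta and BMP signalling, FGF signalling, cell cycle, hypoxia and glycolysis, oxidative phosphorylation, unfolded protein response, immediate early genes, heat shock proteins and cytosolic ribosomal proteins. The 14 cell type lists were macrophage and myeloid, lymphocyte, neutrophil and marrow, erythroid, endothelial, mural and smooth muscle, skeletal muscle, osteoblast and osteocyte, osteoclast, adipocyte, synovial and loose connective tissue fibroblast, Schwann cell and nerve, mast cell, and epithelial. Some genes stand in more than 1 list. The 31 lists with at least 5 genes tested were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. A list's adjusted p is this value unless another test is named. The same test with an estimated correlation, and fry, which asks whether a list's genes move on balance 1 way, were run beside it.

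Named genes had a symbol and met a fixed rule. A panel of 20 genes was fixed for both OA comparisons, of which 18 were in the table. All 18 were tested, but the values of only some are printed here. In each OA comparison and in the control zone comparison, the 10 higher and 10 lower genes of largest fold change were taken among those past the test with at least 5 CPM in the higher group and all 3 libraries of a group above all 3 of the other. Where fewer than 5 qualified in a direction, the 5 of smallest p were taken and given as not past the test. The same rule with 5 per direction, and for the interaction without the separation of libraries, served for the other 2 comparisons. From each list the members past the test with the smallest p were taken, at most 4, or at most 2 if none passed. Departures from the rule, chosen after values were seen, were the 2 ribosomal RNA genes without symbols, the genes of the circadian clock, and the list members named because they passed adjusted over the list alone.

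For a gene at 0 in every library of a group, the fold change is given as a lower bound against a floor of 3 counts over the group. Floors cover counting error only.

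The steps were tested on simulated data with the real genes, means and library sizes, 100 genes changed 2-fold and 100 changed 4-fold. The model recovered 1% and 22% of them in the superficial zone (14247 genes), 0% and 5% in the condylar cartilage (14205 genes), 0% and 0% for the interaction (14214 genes), 1% and 33% between zones in control (14231 genes), and 0% and 0% between zones in OA (14209 genes). Genes that had not been changed made up 0% of 23 calls in the superficial zone and 0% of 5 in the condylar cartilage. They made up 5.56% of 36 calls between zones in control, and the 1 gene called for the interaction had not been changed. A cell cycle list lowered 2-fold was recovered with adjusted p = 2.37e-12, and 0 of the other lists passed by camera. The simulated genes varied independently of each other, so this could not show false list calls from genes that move together. Another number of genes may differ in the real data, so the shares recovered are not the power of the real comparisons.

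The other settings fixed at that stage were DESeq2's median-of-ratios factors, library totals only, other low-count filters, only the libraries of the groups compared, DESeq2 1.42.0, limma-voom with sample quality weights, a block for the replicate number, and leaving out each library in turn. Without OA superficial zone 1 or OA condylar cartilage 3 that OA group holds 1 sample, which is assumed to vary like the samples of the other groups. Settings chosen after the data were seen were 12 separate libraries, offsets for effective gene length, protein-coding genes only, and leaving out both libraries that stood apart.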

Results

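RNA was sequenced from the mandibular condyle of the rabbit temporomandibular joint, the joint of the jaw, after OA had been induced by punching a 2.5 mm hole in the rear outer part of the articular disc. Separate libraries were made from the superficial zone, the fibrous layer at the joint surface, and from the condylar cartilage below it. The 12 libraries formed 4 groups of 3, and totals ranged from 7326255 to 16769536 counts over 14621 genes. Totals were 8646005, 12168450 and 8329096 counts in the control superficial zone and 7326255, 14810886 and 10060508 in the control condylar cartilage. They were 10710067, 15767396 and 16769536 in the OA superficial zone and 15858863, 16099688 and 14291563 in the OA condylar cartilage. Libraries 2 and 3 of the OA superficial zone varied by 2.03 times counting noise at mean counts of 1000 to 10000, and libraries 1 and 2 of the OA condylar cartilage by 2.78 times. The other pairs within groups varied by 34.0 to 678 times. Each of these near-duplicate pairs was counted as 1 sample, so n was 3 in the control groups and 2 in the OA groups. Scaling by library totals only, in place of TMM, moved the median log2 fold change of all genes from 0.05 to −0.24 in the superficial zone and from −0.03 to 0.23 in the condylar cartilage. It moved that median from −0.02 to 0.50 for the difference between zones, from 0.02 to −0.25 between zones in control, and from 0.01 to 0.25 between zones in OA.

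In a principal component analysis the superficial zone libraries lay at −86.1 to −31.7 on PC1 and the condylar cartilage libraries at 17.1 to 68.5, and 2 libraries stood away from their groups. OA superficial zone 1 had COL2A1, the main collagen of cartilage, at 51233 CPM against 2511 and 2583 CPM in its partners. Its mitochondrial messenger RNA was 0.120% of counts against 2.10% and 2.12%, and its long non-coding RNA 5.11% against 2.44% and 2.46%. Control condylar cartilage 3 had COL2A1 at 935 CPM against 42754 and 56682 CPM, and the skeletal muscle actin ACTA1 at 937 CPM against 5.47 and 1.76 CPM. Ribosomal RNA took 0.732% to 3.31% of counts in the 6 OA libraries and 0.107% to 0.378% in the 6 control libraries.

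**Figure D1:**
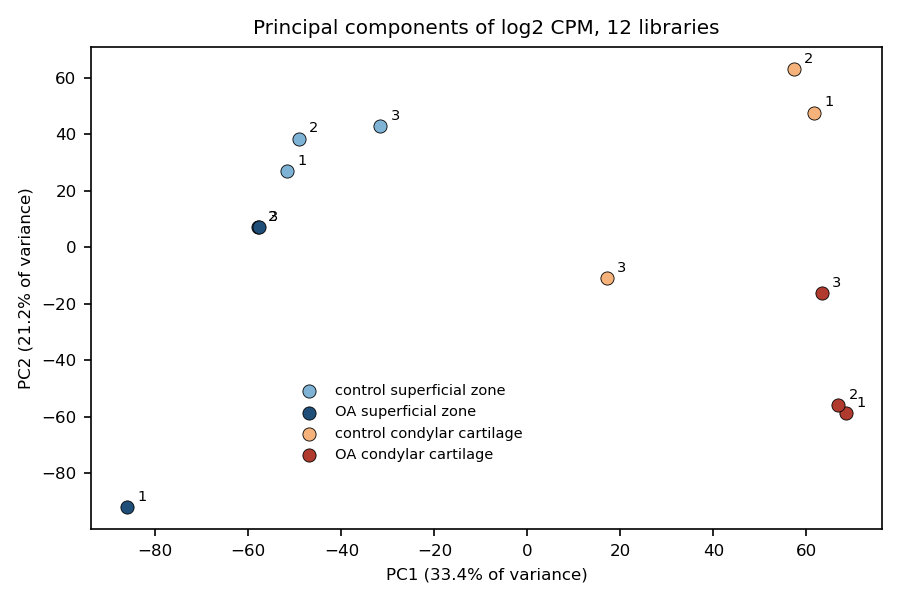
Principal component analysis of log2 CPM for the 12 libraries, with PC1 (33.4% of the variance) on the x axis and PC2 (21.2%) on the y axis and points numbered by replicate. OA superficial zone 1 lies at −86.1 and −92.0, while the near-duplicates OA superficial zone 2 and 3 overlap at −58.0 and 7.17 and at −57.8 and 7.27.

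The first comparison asked which genes differed between OA and control joints in the superficial zone. Genes of cell division were lower in OA: all 24 tested members of the cell cycle list had a negative log2 fold change, with a median of −1.84 and an adjusted p of 6.81e-24 (camera; adjusted p = 0.499 with an estimated correlation; fry 0.0627). TPX2, which organises the mitotic spindle, was at 5.12 ± 0.40 CPM in OA (n = 2) and 26.3 ± 2.68 CPM in control (n = 3), a log2 fold change of −2.37 ± 0.38 that did not pass the test (edgeR adjusted p = 0.063). None of the 24 passed in edgeR over all genes, whereas 20 had an unadjusted p under 0.05 and 20 were lower adjusted over the list alone. With 12 separate libraries 15 passed, in DESeq2 15, and in limma-voom with sample weights 0. The median log2 CPM of the list was 4.31, 4.34 and 4.16 in the control libraries and 2.67, 2.24 and 2.04 in the OA libraries. Outside the list, the lower genes of smallest p were KCNA1, a potassium channel (−5.89 ± 0.92), CDCA7 (−3.15 ± 0.51), the kinetochore gene KNTC1 (−2.57 ± 0.42) and the cytokinesis gene ANLN (−2.52 ± 0.41), each with an edgeR adjusted p of 0.063. KNTC1 was at 5.07 ± 0.29 CPM against 29.9 ± 8.38, and ANLN at 6.45 ± 0.71 CPM against 37.1 ± 7.12.

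**Figure D2:**
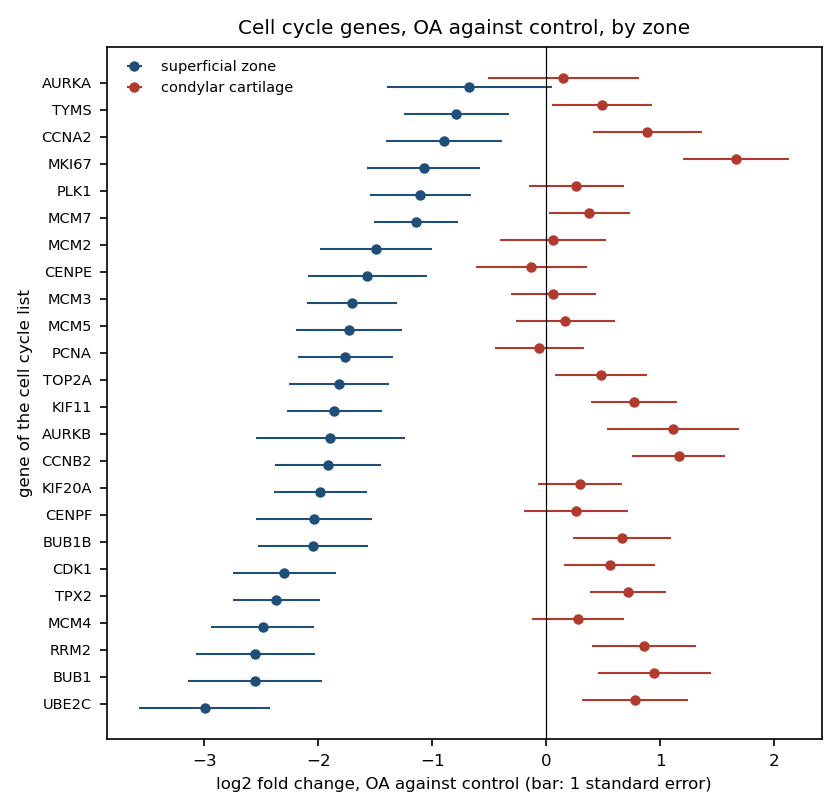
Log2 fold change (OA against control, x axis, bars ± SE) of the 24 tested cell cycle genes in each zone. All 24 lie below 0 in the superficial zone, with a median of −1.84, and 22 lie above 0 in the condylar cartilage, with a median of 0.49.

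At the level of single genes, 3 rose in the OA superficial zone and 0 fell (edgeR), while 1604 had an unadjusted p under 0.05 against 722 by chance. TAPBP (ENSOCUG00000010563), which helps load peptides onto MHC class I, was at 5.49 ± 2.17 CPM (n = 2) and at 0 in control (n = 3), at least 59.1-fold higher (adjusted p = 0.029). It was at 7.18, 2.04 and 5.88 CPM in the OA libraries, so that it differed between the near-duplicates. The other 2 were ribosomal RNA genes without symbols, ENSOCUG00000027166 and ENSOCUG00000034529, beside the higher ribosomal RNA share of all OA libraries, and they were named after their values were seen. Not past the test were ARNTL, a core activator of the circadian clock, at 50.8 ± 13.0 CPM against 13.4 ± 2.36 (1.92 ± 0.31, adjusted p = 0.063), and its relative NPAS2 (1.63 ± 0.32, adjusted p = 0.119). The cyclooxygenase PTGS1 (1.66 ± 0.32) and IDI2 of isoprenoid synthesis (4.46 ± 0.87) had the same adjusted p of 0.119. With 12 separate libraries 163 genes passed (61 higher, 102 lower), in DESeq2 283 (171 and 112), in limma-voom with sample weights 0, and with only the libraries of the groups compared 43. With library totals only 0 passed, and with protein-coding genes only 0, so TAPBP passed in neither. No gene passed without any 1 of control superficial zone 1, 2 or 3, where TAPBP had adjusted p = 0.202, 0.230 and 0.170. TAPBP was also not past the test without OA superficial zone 1 (0.0651) or 3 (0.0775). The number past the test was 5, 7 and 1 without OA superficial zone 1, 2 and 3, and 285 without both libraries that stood apart. The 5 and the 285 rest on 1 OA sample, near-duplicates 2 and 3 summed, whose spread was taken from the other groups.

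Markers of several other cell types were higher as lists in the OA superficial zone, where 10 lists passed by camera and 0 by fry. The neutrophil and marrow list had a median log2 fold change of 5.18 over 10 genes (4.77 with MMP8 at its lower bound), and the erythroid list 2.74 over 8 genes, with adjusted p = 1.47e-06 and 4.47e-04. Their adjusted p was 0.499 and 0.562 with an estimated correlation, and 8 and 7 genes were higher adjusted over the list alone. Macrophage and myeloid genes (16 of 16 positive, median 1.14, adjusted p = 7.06e-06) included TYROBP, CSF1R and C1QC, higher adjusted over the list alone. Skeletal muscle (3.57, adjusted p = 6.60e-05), adipocyte (2.82, 8.09e-04), endothelial (0.46, 0.00634), lymphocyte (1.91, 0.034) and synovial fibroblast lists (1.14, or 0.89 with TIMD4 at its bound, 0.034) also passed. For these 6 lists the adjusted p was 0.499 to 0.582 with an estimated correlation. CIDEA, LPL and CIDEC of the adipocyte list were higher adjusted over the list alone. OA superficial zone 1 stood apart in these lists: its neutrophil and marrow median was 3.75 above its partners and its erythroid median 3.48 above, while its skeletal muscle median was −3.26 from them. Without it the medians were 2.24 for neutrophil and marrow, 0.42 for erythroid, 0.74 for macrophage and myeloid and 0.48 for lymphocyte genes, and the erythroid (adjusted p = 0.384) and lymphocyte (0.639) lists did not pass. Without control superficial zone 2 the lymphocyte (0.0883) and synovial fibroblast (0.180) lists did not pass, nor did the lymphocyte list without OA superficial zone 2 (0.0512).

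The list of matrix-degrading proteases passed in the OA superficial zone, with 16 of 17 genes positive and a median of 0.36 (adjusted p = 0.0127; adjusted p = 0.562 with an estimated correlation), or 11 of 17 and 0.09 when scaled by library totals only. It did not pass without OA superficial zone 1 (0.135) or control superficial zone 2 (0.0665). ADAMTS5, the main aggrecan-cleaving protease, had 1.22 ± 0.33 (edgeR adjusted p = 0.198). Of the 18 panel genes tested none passed in edgeR (adjusted p = 0.198 to 0.995), 5 had an unadjusted p under 0.05, and 0, 1 and 0 passed with 12 separate libraries, DESeq2 and limma-voom. The joint lubricant PRG4 had 0.60 ± 0.43, RUNX2, a regulator of hypertrophy, −1.13 ± 0.36, TIMP1 −0.87 ± 0.35 and PTGS2 −1.54 ± 0.63. COL2A1 had 1.89 ± 1.29, and −1.51 without OA superficial zone 1. Lists that did not pass (adjusted p = 0.0782 to 0.793) had medians of 0.57 for cartilage matrix, 0.73 for chondrocyte regulators, 0.29 for hypertrophy and mineralisation, and 0.60 for superficial zone markers. Of the panel genes in the first 3 of these lists, RUNX2 was negative in the main fit. The others, ACAN (−1.45), COL2A1 (−1.51), SOX9 (−0.96), COL10A1 (−1.50) and MMP13 (−0.57), turned negative without OA superficial zone 1. PHEX (1.22) and BGLAP (3.61) were higher and RUNX2 lower adjusted over the hypertrophy list alone, but BGLAP rested on OA superficial zone 1 (0.21 without it). Medians were 0.63 for inflammatory cytokines and NF-kB targets, 0.61 for interferon response, 0.27 for FGF signalling, 0.06 for TGF-beta and BMP signalling, 0.16 for hypoxia and glycolysis, 0.11 for oxidative phosphorylation and −0.46 for the unfolded protein response. They were 0.35 for immediate early genes, 0.19 for cytosolic ribosomal proteins, 0.64 for mural and smooth muscle, 0.88 for osteoblast and osteocyte (−0.37 without OA superficial zone 1), 1.50 for osteoclast (−0.51 without it) and −0.35 for Schwann cell and nerve. The medians of fibrous matrix (0.06) and Wnt signalling (0.25) were positive and their test pointed down. Protease inhibitors had a median of 0.30 and a mean of −0.34, and heat shock proteins −0.02 and 0.05, with both tests pointing down. When scaled by library totals only, the medians of hypertrophy (−0.16), fibrous matrix (−0.27), protease inhibitors (−0.16), Wnt (−0.28), TGF-beta (−0.20), FGF (−0.02), hypoxia (−0.30), oxidative phosphorylation (−0.07) and ribosomal protein (−0.14) genes turned negative. With median-of-ratios factors the heat shock median turned positive (0.0049). The mast cell (2 genes, median 2.83, or 1.16 with MS4A2 at its bound) and epithelial (3 genes, −1.92) lists were too short to test.

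In the condylar cartilage, the same question gave 118 genes that rose in OA and 7 that fell (edgeR). Genes of neutrophil granules were among those that rose: LTF, the iron-binding granule protein lactoferrin, was at 236 ± 179 CPM in OA (n = 2) and 0.791 ± 1.13 CPM in control (n = 3), a log2 fold change of 8.20 ± 1.33 (adjusted p = 0.023). LCN2 was at 356 ± 277 CPM against 0.842 ± 1.46, and the calcium-binding S100A9 at 176 ± 132 CPM against 0.476 ± 0.824 (8.56 ± 1.49). Of the 10 neutrophil and marrow genes 7 rose, among them CAMP (8.04 ± 1.19), S100A8 (7.77), MPO (6.57) and CXCR2 (6.49), and all 10 were higher adjusted over the list alone. The median was 7.81, also with MMP8 at its bound of at least 278-fold (adjusted p = 7.86e-23; adjusted p = 0.249 with an estimated correlation; fry 0.0283). Of the 8 erythroid genes 6 rose, including the haem synthesis enzyme ALAS2 (4.77 ± 0.77) and AHSP, a chaperone of haemoglobin (6.71). The erythroid median was 5.14 (adjusted p = 3.66e-15; adjusted p = 0.249 with an estimated correlation; fry 0.0287), with 7 genes higher adjusted over the list alone. The median log2 CPM of the neutrophil and marrow list was 6.76, 6.77 and 5.20 in the OA libraries and −2.69, −2.13 and 0.46 in the control libraries. In the erythroid list it was 7.65, 7.62 and 5.88 in OA and 1.06, 0.37 and 2.62 in control.

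**Figure D3:**
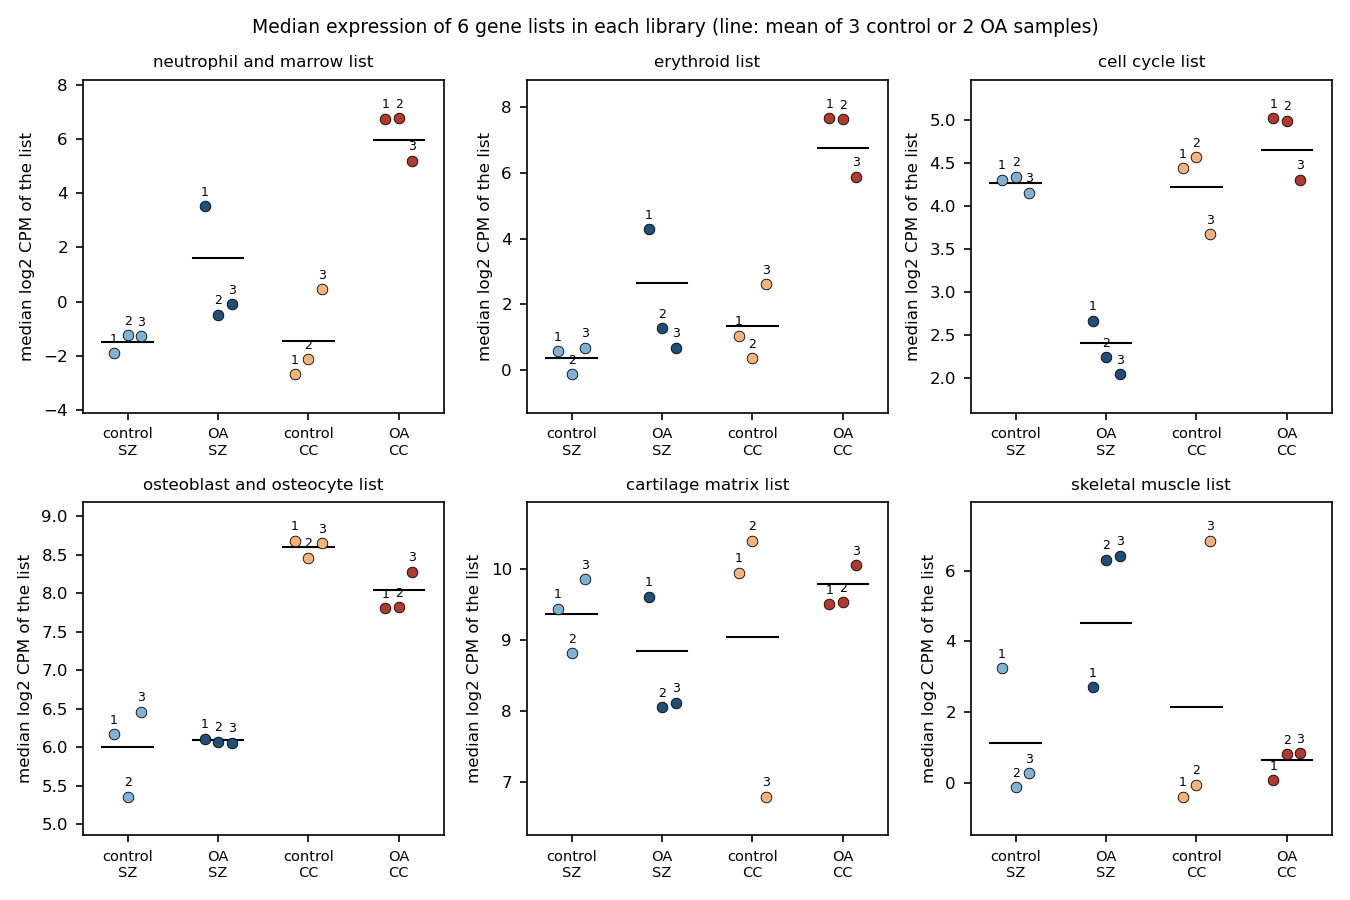
Median log2 CPM (y axis) of 6 gene lists in each library of the 4 groups, with points numbered by replicate and lines at the mean over samples. The neutrophil and marrow list lies between 5.20 and 6.77 in the OA condylar cartilage and between −2.69 and 0.46 in control, and the cell cycle list between 2.04 and 2.67 in the OA superficial zone and between 4.16 and 4.34 in control.

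The 10 named genes that rose also included PRG3, at 14.8 ± 11.4 CPM and at 0 in control, at least 147-fold higher (adjusted p = 0.028), and PRG2 at 69.7 ± 60.1 CPM against 0.037 ± 0.063 (10.70 ± 1.42), both of eosinophil granules. The neutrophil defensin that carries the symbol MCP-1 was at 575 ± 397 CPM against 1.81 ± 2.27 (8.34 ± 1.33). Defensins, PRG2 and PRG3 have near relatives that can share reads, so their single values are uncertain. RHAG of the red cell membrane (8.77 ± 1.53), PGLYRP1 (8.50) and S100A12 (7.86) completed the 10, of 87 genes that met the naming rule. Of those that fell, 4 met it: the lipoprotein gene APOB at 0.940 ± 0.015 CPM against 10.7 ± 5.78 (−3.49 ± 0.62), CRABP2, which binds retinoic acid, at 9.28 ± 0.17 CPM against 35.0 ± 10.9 (−1.92 ± 0.35), MEST (−2.76 ± 0.53) and the RNA-binding IGF2BP2 (−1.60 ± 0.32). SYT7 (−1.58 ± 0.33) did not pass (edgeR adjusted p = 0.055). With 12 separate libraries 441 genes passed, in DESeq2 351, in limma-voom 1540, and with only the libraries of the groups compared 0, and 1335 had an unadjusted p under 0.05. Without control condylar cartilage 1 no gene passed and the 14 named genes had adjusted p = 0.115 to 0.233. Without control condylar cartilage 2, 6 genes passed, and APOB was the only one of the 14 among them, the rest being at 0.0802 to 0.127. Without control condylar cartilage 3, 204 passed, with IGF2BP2 at 0.0732, and 667 passed without both libraries that stood apart. Without OA condylar cartilage 3, which left 1 OA sample, MEST (0.104), APOB (0.139), CRABP2 (0.160) and IGF2BP2 (0.164) did not pass, nor did IGF2BP2 without OA condylar cartilage 2 (0.0516).

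Of the lists in the condylar cartilage 9 passed by camera and 4 by fry. Macrophage and myeloid genes were higher (median 1.45, adjusted p = 2.19e-08; adjusted p = 0.326 with an estimated correlation), with 1 of 16 past the test, the lysozyme gene LYZ (2.91 ± 0.41), and 6 adjusted over the list alone. Lymphocyte genes had a median of 1.63 (adjusted p = 0.00108; adjusted p = 0.431 with an estimated correlation), with JCHAIN (2.99) and MS4A1 (4.32) higher adjusted over the list alone. The adhesion molecule VCAM1 rose (3.02 ± 0.53, adjusted p = 0.026), and in the inflammatory list CXCL8 (5.02) and IL1B (4.39) were higher adjusted over the list alone. That list had a median of 0.07 and did not pass by camera (0.107), though it passed by fry (0.0283). The cell cycle list was higher, with 22 of 24 genes positive and a median of 0.49 (adjusted p = 0.0011; adjusted p = 0.716 with an estimated correlation; fry 0.574). Its median log2 CPM was 5.024, 4.995 and 4.310 in the OA libraries, in which the neutrophil and marrow and erythroid lists were also lowest in library 3, and 4.44, 4.57 and 3.67 in the control libraries, in which those lists were highest in library 3. Oxidative phosphorylation (−0.39, adjusted p = 0.00114) and hypoxia and glycolysis (−0.48, 0.0184) were lower, with adjusted p = 0.716 with an estimated correlation for both and medians of −0.12 and −0.23 when scaled by library totals only. Endothelial genes (−0.51, adjusted p = 0.00114) included ROBO4, lower adjusted over the list alone, and mural and smooth muscle genes had a median of −0.84 (0.00114), with adjusted p = 0.326 and 0.535 with an estimated correlation and medians of −0.26 and −0.58 when scaled by library totals only. Without control condylar cartilage 3, whose skeletal muscle median was 7.97 above its partners and whose cartilage matrix median was −3.22 from them, the cell cycle (0.143), endothelial (0.0529) and mural (0.178) lists did not pass. The hypoxia list did not pass without control condylar cartilage 1 (0.136) or 2 (0.467).

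Of the 18 panel genes tested in the condylar cartilage none passed in edgeR (adjusted p = 0.160 to 0.996), 2 had an unadjusted p under 0.05, and 2, 2 and 3 passed with 12 separate libraries, DESeq2 and limma-voom. PRG4 was at 86.2 ± 36.8 CPM in OA against 29.9 ± 10.8 in control (1.53 ± 0.43, edgeR adjusted p = 0.174, and 0.034 with 12 separate libraries). TIMP1, an inhibitor of matrix metalloproteinases, was at 238 ± 30.7 CPM against 584 ± 167 (−1.29 ± 0.36, edgeR adjusted p = 0.160, and 0.020 with 12 separate libraries). The protease inhibitor list had a median of −0.40 (adjusted p = 0.0633, fry 0.0283), with A2M (−4.51) and TIMP1 lower adjusted over the list alone. Cartilage matrix had a median of −0.76 and a mean of −0.37 while its test pointed up (adjusted p = 0.663), with CILP (2.65) higher and MATN4 (−2.02) lower adjusted over the list alone. These values include control condylar cartilage 3, where COL2A1 and ACAN were at 935 and 435 CPM. Control libraries 1 and 2 had 42754 and 56682 CPM of COL2A1 and 9364 and 11297 CPM of ACAN. The OA libraries lay between, at 12912.5 to 25028.8 CPM of COL2A1 and 3056 to 4657 CPM of ACAN. Chondrocyte regulators (−0.0037, or 0.23 when scaled by library totals only), hypertrophy and mineralisation (−0.38), superficial zone markers (0.45), fibrous matrix (0.03), matrix-degrading proteases (−0.38) and osteoblast and osteocyte genes (−0.29) did not pass. The first 2 of these medians may rest in part on control condylar cartilage 3. It was below its partners in SOX9 (58.4 against 474 and 629 CPM) and COL10A1 (183 against 10376 and 15025 CPM). In MMP13 it was not (2150 against 1952 and 1848 CPM). The skeletal muscle list had a median of −4.51 (adjusted p = 0.12), which turned to 1.83 without control condylar cartilage 3.

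The difference between the zones' OA effects was tested as an interaction. The cell cycle list differed, by a median of 2.30 toward higher values in the condylar cartilage, with 24 of 24 genes positive (adjusted p = 3.29e-24; adjusted p = 0.309 with an estimated correlation; fry 0.0485). TPX2 differed by 3.09 ± 0.50, the replication checkpoint gene CLSPN by 3.16 ± 0.58, KNTC1 by 3.03 ± 0.55, the mitotic kinase NEK2 by 4.20 ± 0.80 and CDCA2 by 2.87 ± 0.55, each with an edgeR adjusted p of 0.245. None passed over all genes, and 21 of the 24 list members were higher adjusted over the list alone. In the other direction, endothelial genes differed by a median of −1.40 (adjusted p = 1.23e-05; adjusted p = 0.309 with an estimated correlation; fry 0.0485). ROBO4, a receptor of endothelial cells, had −2.11 ± 0.42, the converting enzyme ACE −3.44 ± 0.66 and the intermediate filament gene NES −2.93 ± 0.56, each at 0.245. ARHGAP22 had −3.50 ± 0.72 (edgeR adjusted p = 0.246), and TAPBP, at 0 in the control superficial zone, differed by −4.88 or lower (0.245).

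Over all genes 0 passed the interaction test in edgeR, 1265 had an unadjusted p under 0.05, 98 passed with 12 separate libraries (77 higher, 21 lower), 118 in DESeq2 and 0 in limma-voom, and 97 passed without both libraries that stood apart. The lists past the test numbered 11, of which 0 passed with an estimated correlation and 2 by fry. The neutrophil and marrow (2.47, or 2.42 without MMP8) and erythroid (2.10) lists differed upward, and mural and smooth muscle (−1.33) and matrix-degrading proteases (−0.62) downward, with adjusted p = 0.663 with an estimated correlation for each. The skeletal muscle list differed by −8.07 (adjusted p = 1.40e-05; adjusted p = 0.670 with an estimated correlation), beside the ACTA1 levels of 937 CPM in control condylar cartilage 3 and 707 and 696 CPM in OA superficial zone 2 and 3. Adipocyte (−1.99, adjusted p = 0.0433), osteoclast (−1.63, 0.0372), hypoxia and glycolysis (−0.55, 0.0322) and oxidative phosphorylation (−0.56, 0.0156) lists also passed, with adjusted p = 0.670 to 0.862 with an estimated correlation. When scaled by library totals only, the hypoxia median turned to 0.07, and the medians were −0.02 for protease, −0.10 for oxidative phosphorylation, −0.71 for endothelial, −0.91 for mural, −0.82 for osteoclast and −1.38 for adipocyte genes. Without OA superficial zone 1 the neutrophil and marrow list differed by 5.67, the erythroid list by 4.68 and the osteoclast list by 0.21, and without control condylar cartilage 3 the skeletal muscle list differed by −2.07. Adjusted over the list alone, 11 skeletal muscle genes, 5 endothelial genes, 2 proteases (PLAT and PLAU), 1 mural gene and 1 hypoxia gene were lower. Without OA superficial zone 1, adipocyte (0.106), hypoxia (0.106) and osteoclast (0.952) lists did not pass, and without control condylar cartilage 3 adipocyte (0.183) and osteoclast (0.0764) did not. Without control condylar cartilage 1, hypoxia (0.161) and osteoclast (0.0578) did not pass, and without control condylar cartilage 2, hypoxia (0.474) and oxidative phosphorylation (0.0766) did not. The adipocyte list did not pass without control superficial zone 3 (0.0818) or OA condylar cartilage 3 (0.126), the hypoxia list without control superficial zone 3 (0.0879), and the osteoclast list without control superficial zone 1 (0.101).

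Between the zones in control joints, genes of bone and mineralisation were higher in the condylar cartilage. PHEX, an enzyme that regulates mineralisation, was at 406 ± 61.6 CPM in the condylar cartilage (n = 3) and 10.4 ± 1.66 CPM in the superficial zone (n = 3), a log2 fold change of 5.30 ± 0.34 (edgeR adjusted p = 8.24e-05). The osteocyte gene DMP1 was at 428 ± 76.1 CPM against 10.1 ± 3.38 (5.41 ± 0.54, adjusted p = 6.67e-04), and MEPE (5.21 ± 0.93) and the Wnt inhibitor SOST (5.32 ± 1.26, adjusted p = 0.024) were higher with them. Of 11 osteoblast and osteocyte genes 8 were higher (median 4.28), of 16 hypertrophy and mineralisation genes 8 (2.67), and of 8 osteoclast genes 6 (3.12), among them the protease CTSK (2.08) and CALCR (6.05). The first pair had adjusted p = 1.83e-09 and the osteoclast list 1.83e-07, and they had adjusted p = 0.126, 0.126 and 0.175 with an estimated correlation. Adjusted over the list alone, 8, 10 and 7 genes were higher. Cartilage matrix (median 1.59, 10 of 14 genes positive, 2 past the test) was not among the lists past camera. Neither were chondrocyte regulators (−0.36, 6 of 13 positive, 1 past the test). These values include control condylar cartilage 3, where COL2A1 was at 935 CPM. Whether bone in the dissected tissue gave part of the higher bone genes was not tested.

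Some genes of the surface layer and fibrous matrix were lower in the control condylar cartilage. PRG4 had −2.90 ± 0.42, and with CREB5 (−2.25), THBS4 (−2.19), DPT (−2.78) and CLU it made 5 of 9 superficial zone markers past the test (median −1.83, adjusted p = 0.00169; adjusted p = 0.126 with an estimated correlation). Of 18 fibrous matrix genes 6 were lower, among them THBS2 (−2.99), COL14A1 (−3.65) and COL3A1 (−2.04), and LOX, which crosslinks collagen, was higher (1.18). COL1A1, also of this list, did not pass but lay the other way. It was at 163517, 116864 and 273620 CPM in the control condylar cartilage and 78689, 70443 and 62331 CPM in the superficial zone. In all, 6 of the 18 genes had a positive log2 fold change. That list had a median of −1.05 (adjusted p = 0.00274; adjusted p = 0.169 with an estimated correlation). CRABP1, which binds retinoic acid, was at 4.07 ± 1.84 CPM against 102 ± 8.0 (−4.64 ± 0.39, edgeR adjusted p = 4.87e-04). The other lower genes of largest change were C1QTNF4 (−6.56 ± 0.76), COL17A1 (−5.17), FAM180B (−4.99), NEFL (−4.83), LRP1B (−4.78), FAT2 (−4.78), IGLON5 (−4.76), KCNA1 (−4.61) and LRRC4B (−4.56). The other higher ones were CHMP4C (5.87), PLA2G5 (5.37), SALL1 (5.32), BMP3 (5.29), CYFIP2 (5.13) and TAPBP, at 0 in the superficial zone and at least 61.9-fold higher (adjusted p = 0.0013).

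**Figure D4:**
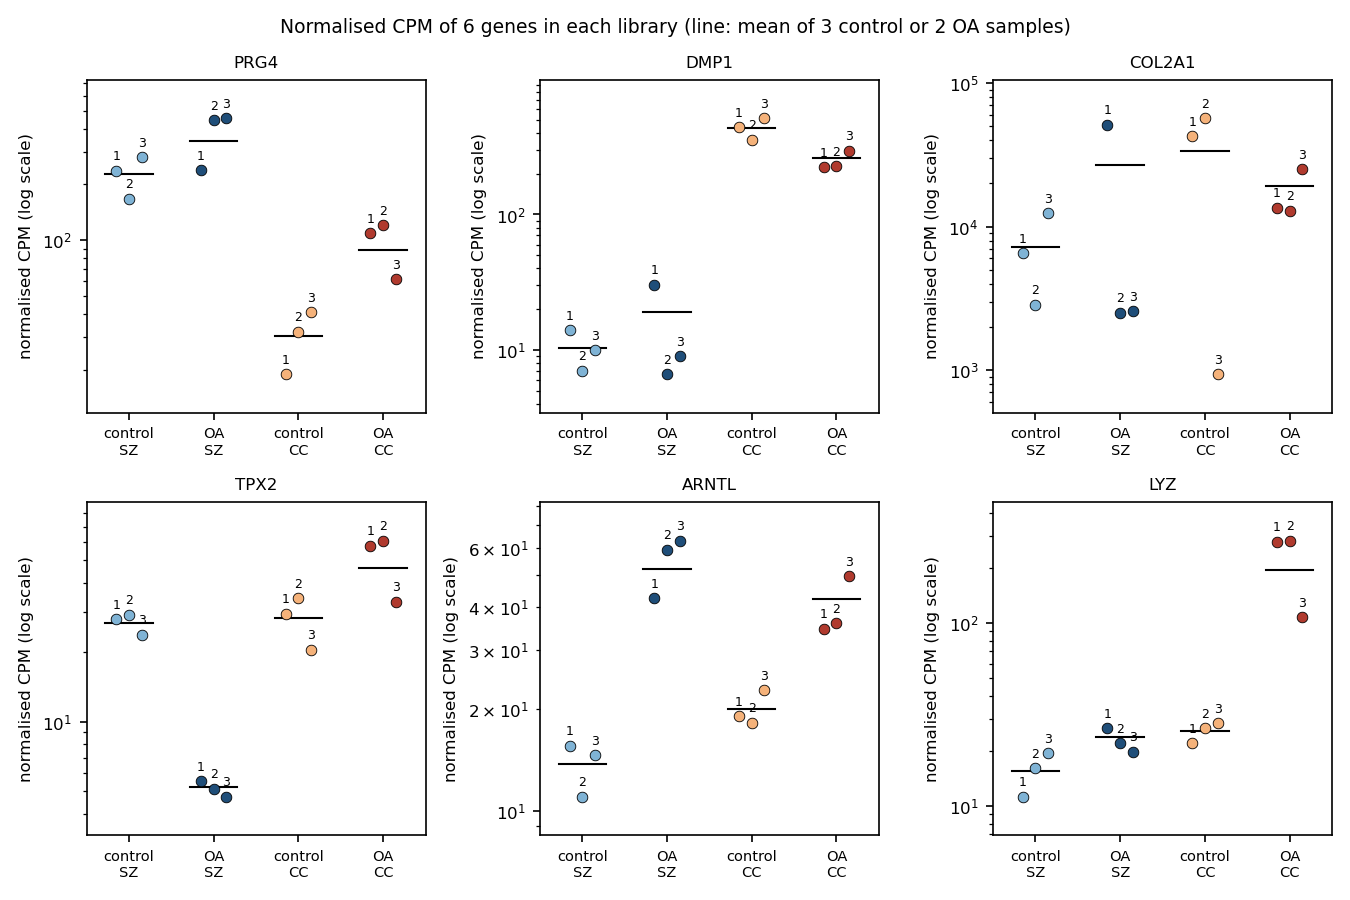
Normalised counts (CPM, log axis) of 6 genes in each library of the 4 groups, with points numbered by replicate and lines at the mean over samples. DMP1 averages 428 CPM in the control condylar cartilage and 10.1 CPM in the control superficial zone, and TPX2 5.12 CPM in the OA superficial zone and 26.3 CPM in control.

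In all, 465 genes were higher and 616 lower in the control condylar cartilage (edgeR), against 330 and 940 when scaled by library totals only. DESeq2 called 1575, limma-voom 3427, the fit of 12 separate libraries 1434 and the fit of only the groups compared 1604. By camera 12 lists passed, and by fry 12. Endothelial genes were higher (6 of 11, median 1.24, adjusted p = 6.69e-05; adjusted p = 0.126 with an estimated correlation), including KDR (1.99) and CDH5 (1.87). Synovial fibroblast genes were lower (3 of 8, among them PDPN and THY1, median −1.88, adjusted p = 1.68e-04) and so were Schwann cell and nerve genes (median −1.56, 0.0066), both with adjusted p = 0.217 with an estimated correlation. Of 18 immediate early genes 5 were lower, such as NR4A1 (−2.33), and EGR2 (2.65) and EGR3 higher (median −0.87, adjusted p = 0.0203; adjusted p = 0.411 with an estimated correlation). IFIH1, a sensor of viral RNA, was higher (2.95) in an interferon list with a median of 0.86 (adjusted p = 0.0385; adjusted p = 0.344 with an estimated correlation). All 28 oxidative phosphorylation genes were positive (median 0.44, adjusted p = 4.59e-04; adjusted p = 0.593 with an estimated correlation), or 17 of 28 when scaled by library totals only, and TAGLN of contractile cells was lower (−2.14) in the mural list (−0.37, 0.038; adjusted p = 0.739 with an estimated correlation). In Wnt signalling, RSPO2 (−3.75) and DKK2 (−3.59) were lower and DKK1 (3.16) higher, with a median of 0.50, a mean of −0.27 and a test pointing down (adjusted p = 0.191). FGF18 was lower (−5.73) and FGF1 higher (2.89). Adjusted over the list alone, 5 superficial zone markers, 8 fibrous matrix genes, 6 synovial fibroblast genes and 6 immediate early genes were lower, and 6 endothelial and 2 interferon genes higher. In the opposite direction were 2 fibrous matrix, 2 immediate early and 1 endothelial gene.

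The number of genes past the test between zones in control was 672, 486 and 722 without control superficial zone 1, 2 and 3, and 521, 815 and 1126 without control condylar cartilage 1, 2 and 3. It was 2452 without both libraries that stood apart. SOST did not pass without control superficial zone 2 (adjusted p = 0.124) or 3 (0.0889). The immediate early list did not pass without control superficial zone 2 (0.0566), and the interferon list did not without control superficial zone 1 (0.0812) or control condylar cartilage 3 (0.165). The mural list did not pass without control superficial zone 1 (0.0628) or control condylar cartilage 1 (0.0563) or 2 (0.318).

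In OA joints, 343 genes were higher and 592 lower in the condylar cartilage than in the superficial zone (edgeR), against 338 and 302 when scaled by library totals only. Cell cycle genes were higher: 13 of 24 passed, among them TPX2 (3.15 ± 0.41), UBE2C (3.79), BUB1 (3.86) and KIF11 (2.71), with a median of 2.31 (adjusted p = 1.62e-14; adjusted p = 0.294 with an estimated correlation) and 20 higher adjusted over the list alone. The transporter SLCO4C1 (7.04 ± 1.11), the leukocyte receptor SLAMF6 (4.87), MS4A3 (4.65), PRG2 (4.52) and MGAM (4.50) were the higher genes of largest change. The growth factor GDF6 (−5.44 ± 0.91), COL6A6 (−5.15), IGLON5 (−5.03), the neurotrophic factor receptor GFRA3 (−4.93 ± 0.62) and the protease ADAMTS16 (−4.82) were the lower ones. Mural and smooth muscle genes were lower, with MCAM, MYH11, TAGLN and ACTA2 past the test (4 of 11, median −2.03, adjusted p = 1.14e-05; adjusted p = 0.294 with an estimated correlation). Osteoblast and osteocyte genes (4 of 11, median 2.81) and hypertrophy and mineralisation genes (6 of 16, 1.57) were higher, both with adjusted p = 1.14e-05. Superficial zone markers (5 of 9, −1.97, adjusted p = 0.00591), fibrous matrix (4 of 18, −0.97, 0.0197) and synovial fibroblast genes (5 of 8, −2.37, 1.48e-04) were lower. These 5 lists had adjusted p = 0.294 with an estimated correlation. Adjusted over the list alone, 9 mural, 5 superficial zone, 5 fibrous matrix and 7 synovial fibroblast genes were lower, and 6 osteoblast, 8 hypertrophy and 1 synovial fibroblast gene higher.

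The erythroid list was also higher in the OA condylar cartilage than in the OA superficial zone (EPB42 and ALAS2 of 8 genes, median 3.68, adjusted p = 6.51e-05), and so was the neutrophil and marrow list (3.68, 1.14e-05), both with adjusted p = 0.331 with an estimated correlation. All 10 neutrophil and marrow genes and 7 erythroid genes were higher adjusted over the list alone. The immediate early (−0.76, adjusted p = 0.0112), Schwann cell and nerve (−1.89, 0.0232), skeletal muscle (−4.85, 0.00406) and osteoclast (1.25, 0.00895) lists passed as well, with adjusted p = 0.331 to 0.567 with an estimated correlation. Of their members 2, 4 and 0 were lower and 3 osteoclast genes higher adjusted over the list alone. The immediate early list did not pass without OA superficial zone 1 (0.0997). By camera 13 lists passed, and by fry 11. With 12 separate libraries 2879 genes passed, in DESeq2 2107, in limma-voom 134, and with only the libraries of the groups compared 0. Without both libraries that stood apart 1751 passed, with 1 OA superficial zone sample. Without OA condylar cartilage 3, which left 1 OA sample of that zone, 104 genes passed, and PRG2, MGAM, GDF6, COL6A6, IGLON5 and ADAMTS16 had adjusted p = 0.0521 to 0.211.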

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

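All tests of an explanation in this part were chosen after the result was seen, except the one on normalisation and the count over other splits of the control samples. The fit without OA superficial zone 1 was itself planned, but what it should show was written after values of that library had been seen. The results below were picked out because the effect of OA differed between the zones by an interaction test of a gene list, with camera at its preset correlation, and 0 of the 11 lists passed with an estimated correlation and 2 by fry.

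Cell cycle genes were lower in the OA superficial zone (median log2 fold change −1.84), and the difference between zones had a median of 2.30. The tables argue against OA superficial zone 1 as the source, since the median was −2.37 without it (SD over genes 0.547), with the OA group then 1 sample of 2 near-duplicates, and against normalisation, since it was −2.20 with library totals only (SD 0.568). Dilution by cells that lack the markers of the superficial zone would lower those markers alike, but they had a median of 0.60 (SD 0.650). This does not bear on added cells that express such markers, and DPT stands in the synovial fibroblast list too. Other changes in the mix of cells were not tested. A change with the disease, or a different age, stage of healing or season of the animals, stays open, because no label bears on it and OA itself was tested only as a group difference. Ribosomal RNA shares did not overlap between the states, at 0.732% to 3.31% in OA and 0.107% to 0.378% in control. Whether the libraries of the states were processed apart was not tested. In the condylar cartilage the list had a median of 0.49 beside higher marrow genes, and whether dividing marrow cells gave that part of the difference was not tested. The pattern is a hypothesis from 2 OA samples, and the list did not pass with an estimated correlation (adjusted p = 0.309 for the difference).

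Neutrophil, marrow and erythroid genes were higher in the OA condylar cartilage, with median differences between zones of 2.47 and 2.10. These depend on OA superficial zone 1, without which they were 5.67 and 4.68. Entry of mature neutrophils alone would leave erythroid genes near their control level, but the erythroid list had a median log2 fold change of 5.14 there (SD over genes 1.83). Marrow or blood in the dissected tissue may account for it: over the 10 samples the deviations of the 2 lists from their group means had a Pearson r of 0.902 (exact permutation within groups, p = 0.0972 over 144 arrangements, 1 relation tested) and a Spearman rho of 0.842 (p = 0.132), with r = 0.804 without both OA superficial zone samples. These p-values leave it open, and marrow contact made by the dissection cannot be told apart from marrow that reached the tissue through the disease, since no label tells how the tissue of either state was dissected. No list of bone genes rose with them: the osteoblast and osteocyte list had a median of −0.29 (SD 0.531, 3 of 11 genes positive) and the osteoclast list −0.24 (0 of 8), or −0.05 (5 of 11) and 0.0093 (4 of 8) with library totals only. Neither scaling gave the rise that a large added share of bone would bring, but a small one is not excluded, since the osteoblast and osteocyte list already lay at 8.47 to 8.69 log2 CPM in control.

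The other lists whose OA effect differed between zones are given as values. The value with library totals only follows each in brackets. Endothelial genes differed by a median of −1.40 (−0.71), mural and smooth muscle genes by −1.33 (−0.91) and skeletal muscle genes by −8.07 (−7.69) on the log2 scale. Osteoclast genes differed by −1.63 (−0.82), adipocyte genes by −1.99 (−1.38) and matrix-degrading proteases by −0.62 (−0.02). Hypoxia and glycolysis genes differed by −0.55 (0.07) and oxidative phosphorylation genes by −0.56 (−0.10). The osteoclast test turned upward without both libraries that stood apart, and skeletal muscle genes differed by −2.07 without control condylar cartilage 3.

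For the count of 1081 genes between zones in control, 1 of the 10 splits of the 6 samples, the real one, gave as many, and the highest of the other splits gave 0. With 10 splits no share under 0.05 can be had.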

How the results depend on the processing

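The settings with 12 separate libraries, effective-length offsets, protein-coding genes only, and without both libraries that stood apart were chosen after the data were seen. Counts of genes past the test stayed within 1.5 times the main count in all 5 comparisons with median-of-ratios factors, with either other low-count filter and with effective-length offsets. Leaving aside the fits without 1 library, 3289 gene and list values kept their direction and side of the threshold, 191 passed it newly, 264 no longer passed and 24 changed direction. For lists this covers those past the test, by the direction of camera, which compares a list with all other genes. List medians are not in these counts, and some turned with library totals only, among them hypoxia and glycolysis for the difference between zones, where the median was 0.07 while the test still pointed down and passed. Of the counts over the other settings 59 stayed within 1.5 times and 33 did not. In the simulated data, with 100 genes changed 4-fold and 100 changed 2-fold, at most 33% of 4-fold changes were recovered in any comparison. These shares hold for that setting only. Between zones in OA 0% was recovered, while the same model called 935 genes in the real data. A gene not past the test is undecided. For every count and value below the cause was not tested, except that 12 separate libraries and the block fits hold more samples and that protein-coding genes only leaves out the 2 ribosomal RNA genes. TAPBP also did not pass in the superficial zone with protein-coding genes only, and the cause of that was not tested.

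With 12 separate libraries, 163 genes passed in the superficial zone, 441 in the condylar cartilage, 98 for the difference between zones and 2879 between zones in OA. In DESeq2 the counts were 283, 351, 118 and 2107. With limma-voom and sample weights they were 0 in the superficial zone, 1540 in the condylar cartilage, 3427 between zones in control and 134 between zones in OA. With only the libraries of the groups compared, 43 passed in the superficial zone, 0 in the condylar cartilage and 0 between zones in OA. In the superficial zone 0 passed with library totals only and 0 with protein-coding genes only. With an estimated correlation, 0 lists passed in the superficial zone, 0 in the condylar cartilage, 0 for the difference, 0 between zones in control and 0 between zones in OA. Without both libraries that stood apart, 285 genes passed in the superficial zone, 667 in the condylar cartilage, 97 for the difference, 2452 between zones in control and 1751 between zones in OA.

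Same-numbered samples of different groups had correlations of −0.261 to 0.289, and samples of unequal number reached 0.297. These values neither show nor exclude that equal numbers share an animal. With the replicate number as a block in the fit of 12 separate libraries, 132 genes passed in the superficial zone, 324 in the condylar cartilage, 92 for the difference and 2445 between zones in OA, and with a block within disease state 73 for the difference and 2155 between zones in OA. With the block ACAN (−0.24), SOX9 (−0.10) and MMP13 (−0.020) changed direction in the superficial zone.

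The other changes of direction in these counts concerned genes that did not pass the test and, by camera, the osteoclast list, which passed in the main analysis (adjusted p = 0.0372). With library totals only, the superficial zone gave SOX9 −0.13, MMP3 −0.14, MMP13 −0.35 and ADAMTS4 −0.24, and with 12 separate libraries MMP13 −0.087. With limma-voom, SFRP2 had −0.16 in the superficial zone, and RUNX2 −0.0057 and PTGS2 −0.18 in the condylar cartilage. Without both libraries that stood apart, the superficial zone gave ACAN −1.49, COL2A1 −1.56, COL10A1 −1.56, COL1A1 −0.62, SOX9 −0.99, MMP13 −0.61, ADAMTS4 −0.21 and GREM1 −0.45. The condylar cartilage gave COL3A1 −0.012, RUNX2 −0.050 and PTGS2 −0.058 there, MMP9 differed between zones by 0.055, and the osteoclast list of that difference turned upward (adjusted p = 0.841).

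Without OA superficial zone 1, alone or with control condylar cartilage 3, and without OA condylar cartilage 3, 1 OA group held a single sample, assumed to vary like the other groups. Without 1 library at a time, the count was 0 to 7 in the superficial zone, 0 to 204 in the condylar cartilage, 486 to 1126 between zones in control and 104 to 937 between zones in OA. In the superficial zone ACAN ranged from −1.45 to 0.63, ADAMTS4 from −0.17 to 0.14, COL10A1 from −1.50 to 2.48, COL1A1 from −0.58 to 1.17, COL2A1 from −1.51 to 2.46 and GREM1 from −0.41 to 0.99. MMP13 ranged there from −0.57 to 0.72, MMP3 from −0.27 to 0.46, NOS2 from −0.45 to 0.0016 and SOX9 from −0.96 to 0.55. In the condylar cartilage COL3A1 ranged from −0.0022 to 0.75, GREM1 from −0.51 to 1.76, MMP3 from −1.07 to 0.14, PTGS2 from −0.057 to 0.52, RUNX2 from −0.042 to 0.16, SFRP2 from −0.22 to 1.56 and SOX9 from −0.99 to 0.15. The difference between zones of MMP9 ranged from −3.03 to 0.16.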

Other observations

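The list of circadian clock genes and its test were chosen after the values of ARNTL and NPAS2 had been seen.

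Of 13 genes of the circadian clock, none passed the test over all genes in edgeR in either zone. In the superficial zone the activators ARNTL (1.92), NPAS2 (1.63) and the repressor NFIL3 (2.00) had positive log2 fold changes, while the clock outputs and repressors CIART (−2.10), PER2 (−1.26), HLF (−0.91), NR1D2 (−0.68), PER1 (−0.65) and TEF (−0.28) had negative ones. In the condylar cartilage ARNTL had 1.08, NFIL3 1.09 and NPAS2 0.60, against −1.15 for CIART, −1.05 for PER2, −0.95 for PER1, −0.90 for TEF, −0.52 for HLF and −0.048 for NR1D2. CRY1 (−0.77 and −0.30) and NR1D1 (0.25 and 0.41) went against the phase of ARNTL in both zones, CRY2 did so in the superficial zone only (0.42 and −0.29), and CLOCK had 0.055 and 0.11.

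Collection of the OA and control tissue at another time of day may account for these values. The 11 genes other than ARNTL and NPAS2, of 13 in the table out of 16 fixed, had a median log2 change, signed by the phase of ARNTL, of 0.65 in the superficial zone (SD 0.936, 8 of 11 with ARNTL) and 0.52 in the condylar cartilage (SD 0.575, 9 of 11). By limma's fry their adjusted p over both zones was 0.0356 and 0.0385. ARNTL and NPAS2 drew attention in these same samples, so leaving them out does not make this an independent test. No label gives a time of collection for either state, so this cannot be told apart from a change of the clock with OA.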
